A study of Mus musculus with 19 samples.

How the data were processed

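The deposited file held 1 value per gene and library in TPM from the authors, and no counts were made here. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.14 to mm10 and transcripts were quantified with Cufflinks 2.2.1. The tool that made the TPM values and the gene annotation it used were not given in the sources used here. Per the labels, RNA was extracted with RNA iso Plus and libraries were made with a SMARTer mRNA-Seq kit. The design was written for FPKM, and the file held TPM, so the same limma test was used on TPM. The table held 56066 genes, 55487 with Ensembl identifiers and 579 assembled by the authors, and 2 columns that belonged to no sample of the series and were not used.

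Of 19 libraries 18 were fitted together, and P21 library 63 was left out because its genotype label and its title disagreed. Genes with at least 1 TPM in at least 3 libraries were tested (14812), as log2(TPM + 1). R 4.3.3, limma 3.58.1 (lmFit, eBayes with trend) and version 1.17.8 of the data.table package were used with a model of group and title style. Sex was not a term of the model. P-values were adjusted with the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 passed. The difference between the P21 and P7 effects was an interaction contrast of the same model. Named genes were Pdpk1 and Pdk1 and, per comparison, up to 8 genes per direction with the largest changes among passing genes with a mean of at least 5 TPM in the higher group and no overlap of the libraries of the 2 groups; sex genes and genes with placeholder names were left out by the rule. For each gene list described, the same rule named up to 4 members with the smallest p in that comparison, and up to 2 where no member passed. Some genes that the rule names are not reported here. Genes outside this rule are said in the text to be chosen after their values were seen, apart from Xist and Ddx3y, which belong to a list of sex genes fixed before the data were examined. The comparisons, the alternatives, the naming rule and 47 gene lists were fixed before the data were examined; 45 lists had at least 3 members tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry; member counts adjusted over the list alone used Benjamini-Hochberg over the members only.

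Alternatives were median-ratio scaling, quantile normalization, removal of mitochondrial and haemoglobin genes, a pseudocount of 0.1, a filter of 5 TPM, no filter, a 2-fold threshold, array quality weights, models without the title style or within 1 style, a replicate block, library 63 placed as cKO or WT, and each library left out in turn. The genes removed were those with the mt- prefix and those whose symbols start with Hba or Hbb. Calls were compared with splits of the same libraries into other groups, all of them or 100 drawn. Simulated data with 200 changed genes of 14812 were run through the same step: it called 157 genes at P7 (5 false), 138 at P21 (8 false), 145 for P7 against P1 (11 false) and 162 for P21 against P7 (9 false), with 0 of wrong sign. The simulated changes were set only in better expressed genes, with noise independent between genes and no shift of the median gene. Their recovery does not give the power for low genes. Gene positions are from GENCODE M21 on mm10.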

Results

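RNA was sequenced from 19 mouse heart libraries to compare hearts with a conditional knockout (cKO) of PDK1, a kinase gene product, with wild-type (WT) hearts after birth. The labels gave 3 WT libraries at postnatal day 1 (P1), 5 at P7 and 4 at P21, and 3 cKO libraries at each of P7 and P21. The series design text says P0 where the labels say P1, and the labels were followed here. The remaining P21 library, numbered 63, had a cKO genotype label under a title without the KO that the other cKO titles carry, and it was left out of the groups. The authors' own mean column for P21 WT was the mean of libraries 57, 60 and 63, so it counted library 63 as WT. WT titles had 2 styles: all 3 P1 titles, 2 of the P7 titles and 2 of the P21 titles held a letter code, and 3 P7 and 2 P21 titles were plain numbers, as cKO titles were. Gene levels were TPM, which keep no depth, so the depth of each library was unknown. Between 12422 and 13797 genes per library reached 1 TPM. The 10 most abundant genes held 40.6% ± 0.836 of all TPM (SD, n = 4) in P21 WT and 35.8% ± 0.09 (n = 3) in P21 cKO, against 32.4% ± 0.961 (n = 5) in P7 WT and 32.1% ± 1.27 (n = 3) in P7 cKO. Transcripts of the mitochondrial genome, taken by their mt- prefix, held 23.5% ± 0.76 in P21 WT and 20.3% ± 0.0802 in P21 cKO. They held 18.3% ± 0.76 in P7 WT and 18.2% ± 0.968 in P7 cKO. This share left out Gm28661, Gm28437, Gm10222, Gm28438 and Gm10925, chosen after their values were seen. These were among the 10 genes with the highest mean TPM over the 18 libraries. Whether they shared reads with mitochondrial genes was not tested.

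The labels did not say whether each library came from a separate animal, so P-values measured the spread between libraries. Fold changes were differences of log2(TPM + 1), a scale that understates the change of low genes. The median log2 change of all 14812 genes tested was 0.22 between P21 cKO and P21 WT and -0.47 between WT P21 and WT P7. Medians and member values of gene lists in those comparisons are given relative to that median gene. Counts of list members called higher or lower, or said to rise or fall, are not. They rest on tests of the unshifted log2 change against 0. Log2 changes with a library left out are unshifted, and the unshifted value from all 18 libraries is given beside them, except for Chchd3, Tomm40 and Immt.

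PDK1 can name the product of Pdpk1, the kinase that activates AKT, or of Pdk1, a kinase that inhibits pyruvate dehydrogenase, and the labels did not say which was deleted. Pdpk1 (ENSMUSG00000024122; mm10, chromosome 17, 24073680 to 24150924) stood at 8.09, 7.98 and 7.95 TPM in the 3 P7 cKO libraries. The P7 WT libraries with plain numbers had 8.09, 7.96 and 9.32 TPM, and those with letter codes 11.9 and 11.63 TPM. At P21, Pdpk1 was at 5.54, 5.55 and 4.95 TPM in cKO and at 7.65, 7, 6.17 and 6.6 TPM in WT. Each cKO library lay below each WT library. Library 63 had 6.23 TPM. The P1 WT libraries had 10.57, 12.11 and 8.19 TPM. The limma test did not separate the groups: the log2 change of Pdpk1 was -0.12 ± 0.11 (SE) at P7 (adjusted p = 1) and -0.15 ± 0.12 at P21 (adjusted p = 0.366). At P21 it was -0.37 after median-ratio scaling (adjusted p = 0.02) and -0.39 after quantile normalization (adjusted p = 0.0137). Pdk1 (ENSMUSG00000006494; chromosome 2, 71873224 to 71903858) was at 38.7 ± 1.7 TPM in P7 cKO and 40.6 ± 3.16 TPM in P7 WT (log2 change -0.05, adjusted p = 1). At P21 it was at 34.1 ± 3.18 TPM (n = 3) in cKO and 26.5 ± 2.12 TPM (n = 4) in WT, a log2 change of 0.36 (limma adjusted p = 0.0473) that no longer passed when any of 14 of the 18 libraries was left out (0.29 to 0.42 without them). Values covered whole genes, so a deleted exon could not be seen.

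**Figure D1:**
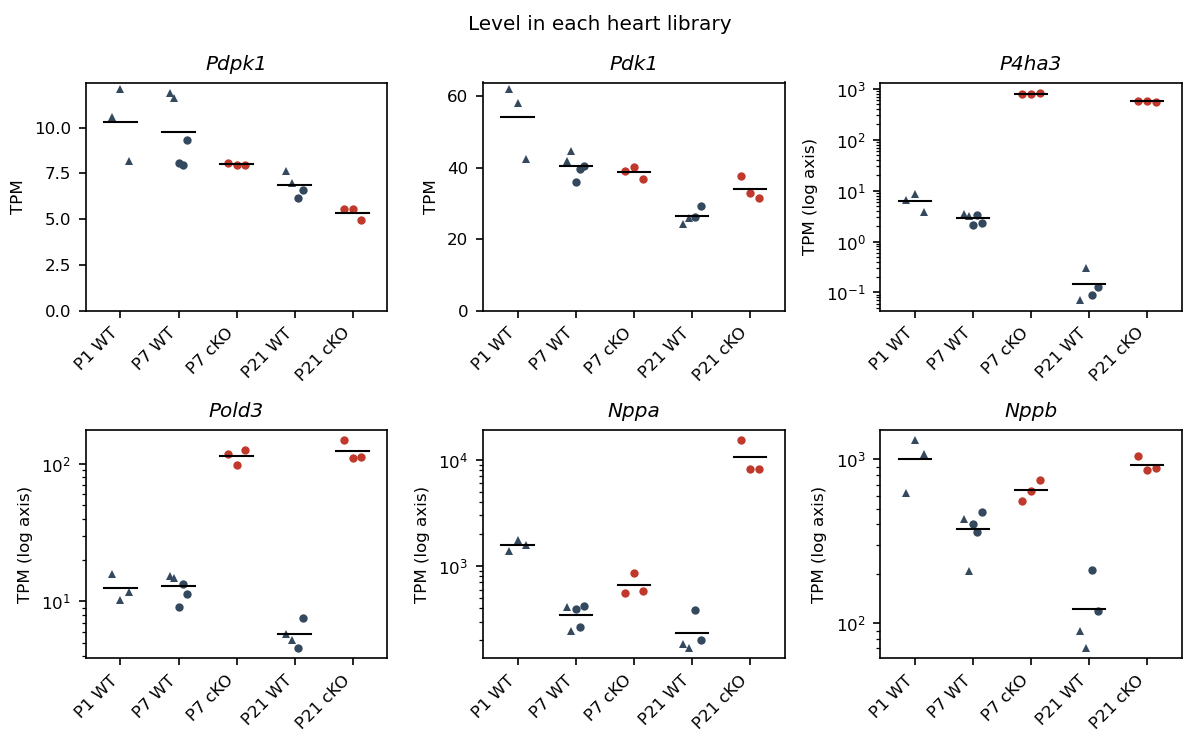
TPM of 6 genes in each of the 18 grouped libraries (vertical axes; linear for Pdpk1 and Pdk1, log for the others), with triangles for letter-code titles, circles for plain numbers, red for cKO and a line at each group mean. P4ha3 had a mean of 799.5 TPM in P7 cKO and 564.1 TPM in P21 cKO against 2.89 and 0.148 TPM in WT, while Pdpk1 overlapped between the P7 groups.

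At P7, cKO hearts had far higher messenger RNA of P4ha3 and Pold3, a pair of genes on chromosome 7, than WT hearts. P4ha3, which encodes a catalytic subunit of collagen prolyl 4-hydroxylase (ENSMUSG00000051048; mm10, chromosome 7, 100285520 to 100319699), was at 799.5 ± 30 TPM in cKO (n = 3) and 2.89 ± 0.617 TPM in WT (n = 5), with a log2 change of 7.78 ± 0.18 (SE; limma adjusted p = 2.15e-13). Pold3, which encodes a subunit of DNA polymerase delta (ENSMUSG00000030726; 100082111 to 100121565), was at 114.5 ± 14.1 TPM in cKO and 12.8 ± 2.56 TPM in WT, a log2 change of 3.15 ± 0.19 (adjusted p = 1.73e-07). The only other gene to pass was Gm6139, a processed pseudogene on chromosome 5 that was chosen after its values were seen, at 2.64 ± 0.484 TPM in cKO and 0.242 ± 0.333 TPM in WT (log2 change 1.48, adjusted p = 0.0299). The genes between and beside P4ha3 and Pold3, also chosen after their values were seen, did not pass: Lipt2 had a log2 change of -0.64, Kcne3 of -0.76, Pgm2l1 of -0.41 and Ppme1 of -0.52, and the non-coding Gm35082 of 1.14. In library 63, P4ha3 was at 0.05 TPM and Pold3 at 5.29 TPM, within or below the range of the P21 WT libraries.

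**Figure D2:**
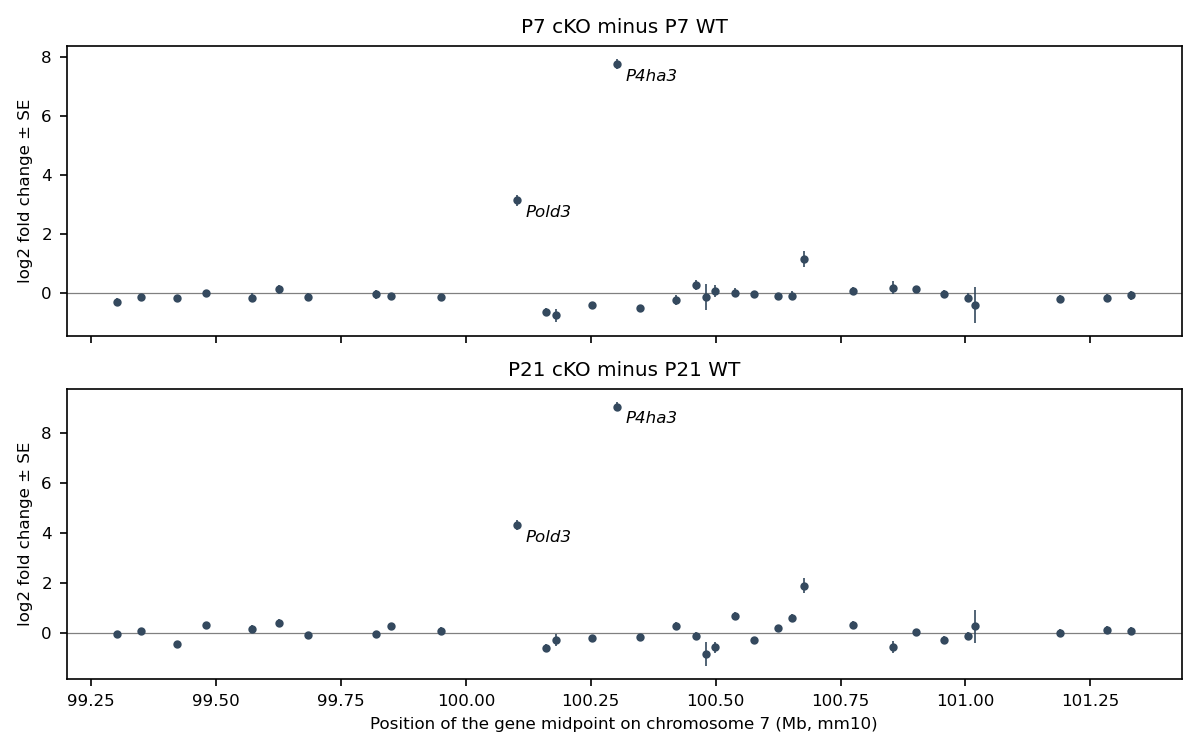
Log2 fold change ± SE (vertical axes) of each gene tested within 1 Mb of P4ha3 against the position of its midpoint on chromosome 7 (horizontal axis, Mb, mm10), at P7 (top) and P21 (bottom). P4ha3 reached 7.78 and 9.05 and Pold3 3.15 and 4.30 at the 2 ages, while the genes that lie between them, such as Lipt2 with -0.64 and -0.61, were near or below 0.

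Of 45 gene lists tested with limma's camera, 3 passed at P7, none with a member that passed on its own. Fetal and stress genes moved up relative to other genes, with a median 0.12 above the median gene over 24 members. Clu had a log2 change of 0.28 and Nppa, which encodes atrial natriuretic peptide, of 0.80 (limma adjusted p = 0.705 and 1). Endothelial markers lay 0.09 above the median gene over 14 members, among them Esam with 0.16 and Emcn with 0.09. Genes of cholesterol synthesis lay 0.09 below it over 21 members, among them Hsd17b7 with -1.31 and Hmgcs1 with -0.20. Each list had a camera adjusted p of 0.0357 and an adjusted p of 0.966 with an estimated correlation, and the self-contained test fry passed 0 lists. Members with an unadjusted limma p under 0.05 numbered 4 of the fetal and stress genes, 2 of the cholesterol genes and 0 of the endothelial markers. Adjusted over the list alone, 1, 1 and 0 passed. The fetal list no longer passed without any of 7 single libraries (adjusted p 0.0587 to 0.308), the cholesterol list without any of 5 (0.0587 to 0.134) and the endothelial list without any of 8 (0.0533 to 0.229).

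Across all 14812 genes at P7, limma called 3 at an adjusted p under 0.05, all higher in cKO, and 494 had an unadjusted p under 0.05. In simulated data the same step recovered 92% of 2-fold and 60% of 1.4-fold changes at P7, all set in better expressed genes. The count was 2 without P7 WT 1 and 7 without P7 cKO 75, and it was 0 when library 63 was added to the P21 cKO group, which shares the estimate of spread, and 4 when it was added to the P21 WT group, 2 higher and 2 lower. With library 63 as cKO, P4ha3 kept its log2 change of 7.78 with an adjusted p of 0.234. That library had P4ha3 at 0.05 TPM, against 542.49 to 575.06 TPM in the P21 cKO libraries. This setting thus mixed unlike libraries in 1 group.

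At P21, cKO hearts had higher messenger RNA of the natriuretic peptide genes Nppa and Nppb and of Ankrd1, and lower messenger RNA of Tnni2, Myl1 and Ogdhl, than WT hearts. Nppa (mm10, chromosome 4, 148000722 to 148002079) was at 10560 ± 4060 TPM in cKO (n = 3; 15241, 8252 and 8176 TPM) and 234.9 ± 100 TPM in WT (n = 4), a log2 change of 5.31 ± 0.30 (SE; limma adjusted p = 5.55e-08). Its neighbour Nppb (chromosome 4, 147985788 to 147987205), which encodes B-type natriuretic peptide, was at 928 ± 99.3 TPM against 122 ± 62.3 TPM (log2 change 2.69 ± 0.30, adjusted p = 7.8e-05). Ankrd1, which encodes a cardiac ankyrin repeat protein induced by stretch, was at 1048 ± 241 TPM against 237 ± 96.9 TPM (2.12 ± 0.34, adjusted p = 9.96e-04). P4ha3 was at 564.1 ± 18.7 TPM against 0.148 ± 0.105 TPM (9.05 ± 0.19, adjusted p = 6.28e-14) and Pold3 at 124 ± 21.8 TPM against 5.77 ± 1.26 TPM (4.30 ± 0.20, adjusted p = 4.99e-09). Bex1 (2.64) and Tmem171 (2.07) were also higher. Mrpl48-ps, a processed pseudogene on chromosome 4 with a log2 change of 2.61, is uncertain, since it can share reads with Mrpl48, a gene chosen after its values were seen, which lies near P4ha3 and had a log2 change of -0.30.

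Among the genes lower in P21 cKO hearts, Tnni2, which encodes fast skeletal troponin I, was at 1.38 ± 0.603 TPM against 7.77 ± 0.744 TPM in WT (log2 change -1.85 ± 0.21, limma adjusted p = 9.67e-05). Myl1, which encodes a fast myosin light chain, was at 13.1 ± 4.06 TPM against 42.6 ± 2.32 TPM (-1.67). Ogdhl, which encodes a 2-oxoglutarate dehydrogenase-like enzyme (mm10, chromosome 14, 32322019 to 32348151), was at 15.1 ± 3.64 TPM against 53.0 ± 7.89 TPM (-1.84). Csdc2 (-1.56), Lrtm1 (-1.40) and Igsf1 (-1.39) were also lower, and Lrtm1 and Igsf1 each lost that call in 1 of 32 settings. Uckl1os, with a log2 change of -1.99, is an antisense gene and is uncertain, since the sources do not say that counting used the strand.

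Genes of the extracellular matrix and of stromal and vascular cells were higher in P21 cKO hearts relative to the median gene. Of 40 matrix genes, 28 were higher and 0 lower (30 and 0 adjusted over the list alone), and 17 were higher after median-ratio scaling. Postn, which encodes the matrix protein periostin, lay 0.80 above the median gene, Col3a1 0.60, Sparc 0.44 and Timp1 0.36. Of 14 fibroblast markers, 7 of them also matrix genes, 12 were higher (12 adjusted over the list alone; 8 after median-ratio scaling), such as Pcolce (0.38) and Dcn (0.28). Of 14 endothelial markers 11 were higher (13 adjusted over the list alone; 1 after median-ratio scaling), such as Pecam1 (0.25), Tie1 (0.26) and Esam (0.28). Of 12 mural cell markers 6 were higher (7 adjusted over the list alone; 2 after median-ratio scaling), such as Cspg4 (0.52) and Pdgfrb (0.53). Camera adjusted p-values were 3.55e-07, 5.17e-05, 6.26e-04 and 0.0168. The adjusted p with an estimated correlation was 0.390 for the matrix and fibroblast lists, 0.238 for the endothelial and 0.337 for the mural list. The mural list no longer passed without P21 WT 57 (adjusted p = 0.0638). Macrophage markers moved the other way, with a median of 0.33 below the median gene over 14 members (adjusted p = 8.28e-05, and 0.218 with an estimated correlation), among them Folr2 at -0.85 and C1qa at -0.49, but 0 members passed in limma, 0 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone.

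Several lists of mitochondrial and fuel-use genes lay lower in P21 cKO hearts relative to the median gene, and others of the same kind did not pass. Of 28 genes of fatty acid oxidation, 9 were lower and 1 higher (10 and 2 adjusted over the list alone; 15 and 0 after median-ratio scaling), with Slc25a20, the acylcarnitine carrier gene, at -0.75, Acaa2 at -0.73, Acads at -0.69 and Hadh at -0.68. Of 17 genes of the citric acid cycle and pyruvate dehydrogenase, 3 were lower and 1 higher (4 and 1 adjusted over the list alone; 13 and 1 after median-ratio scaling), with Idh3a at -0.49 and Idh2 at 0.29. Of the other 2 lower genes, Suclg1 lost its call without P21 WT 57, P21 cKO 55 or P21 cKO 64 (unshifted log2 changes -0.28, -0.24 and -0.26, against -0.26 with all libraries). Pdhx lost its call without P21 WT 2, P21 WT 3, P21 WT 57, P21 cKO 55 or P21 cKO 59 (-0.30, -0.28, -0.35, -0.29 and -0.26, against -0.30). Of 13 genes of the mitochondrial genome 3 were lower (3 adjusted over the list alone; 4 after median-ratio scaling), and mt-Nd4 lay at -0.61. The other 2, mt-Cytb and mt-Nd2, both lost their calls without P21 WT 57 (unshifted log2 changes -0.43 and -0.37, against -0.46 and -0.34 with all libraries) and without P21 cKO 59 (-0.43 and -0.34), and mt-Nd2 also without P21 cKO 55 (-0.28). The nuclear respiratory chain lists lay 0.23 to 0.33 below the median gene with few members called: for complexes II and III 3 of 13 were lower, among them Uqcrc1 at -0.48, for complex I 0 of 36, for complex IV 0 of 14, and for complex V 1 of 16 was higher, Atpif1, an ATPase inhibitor gene, at 0.59. The call of Uqcrc1 was lost in 4 of 32 settings. Of the other 2 lower genes of complexes II and III, Uqcrb lost its call without any of 11 libraries (unshifted log2 changes -0.21 to -0.17, against -0.20 with all libraries) and Uqcrfs1 without any of 15 (-0.20 to -0.14, against -0.18). Adjusted over the list alone, 3, 0, 0 and 1 passed, and 2 complex I members, both higher in cKO, and 0 complex IV members had an unadjusted p under 0.05. After median-ratio scaling 7, 4 and 0 members of these first 3 groups were lower, and 5 of complex V. Of 36 mitochondrial ribosome genes 1 was lower (0 adjusted over the list alone; 12 after median-ratio scaling), Mrps34 at -0.61, a call that ended without P21 WT 57, P21 cKO 55 or P21 cKO 64 (unshifted log2 changes -0.34, -0.34 and -0.40, against -0.39 with all libraries). Of 22 glycolysis genes 3 were lower and 1 higher (3 and 1 adjusted over the list alone; 9 and 1 after median-ratio scaling): Slc2a1, the GLUT1 transporter gene, lay at 0.71 and Eno3 at -0.65, which no longer passed without P21 cKO 59 (unshifted log2 change -0.39, against -0.43 with all libraries). The other 2 lower genes also lost calls, Pkm without P21 cKO 55 (-0.21, against -0.31) and Gapdh without P21 WT 2, P21 cKO 59 or P21 cKO 64 (-0.25, -0.24 and -0.28, against -0.27).

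The camera adjusted p was 1.78e-14 for fatty acid oxidation, 2.99e-07 for the citric acid cycle, 1.68e-07 for mitochondrial genome genes, 2.11e-07 for complex I, 2.41e-06 for complexes II and III, 0.00305 for complex IV, 0.00109 for complex V, 3.12e-08 for the mitochondrial ribosome and 4.48e-05 for glycolysis. With an estimated correlation each adjusted p was over the threshold: 0.103, 0.134, 0.0597, 0.474, 0.218, 0.490, 0.390, 0.323 and 0.218 in the same order. Fry passed fatty acid oxidation and the mitochondrial genome genes (adjusted p = 0.0124 each). On the unshifted scale the mean log2 change of complex V genes was above 0, at 0.10, while their median lay below the median gene.

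Other mitochondrial and fuel-use lists did not pass camera at P21. Of 12 genes of ketone and branched-chain amino acid use 1 was higher and 0 lower (1 and 0 adjusted over the list alone; 1 and 2 after median-ratio scaling; camera adjusted p = 0.286), Bdh1 at 1.19 relative to the median gene. Of 20 regulators of mitochondrial biogenesis 3 were higher and 0 lower (3 and 0 adjusted over the list alone; 1 and 2 after median-ratio scaling; 0.99), with Polg at 0.31. Esrrb, at 0.51, lost its call without P21 WT 57 or P21 cKO 64 (unshifted log2 changes 0.59 and 0.65, against 0.73 with all libraries), and Ppargc1b, at 0.18, without any of 7 libraries (0.38 to 0.42, against 0.40). Of 22 genes of mitochondrial import and cristae 3 were higher and 1 lower (3 and 1 adjusted over the list alone; 0.0595), with Timm10 at 0.36. The calls of Chchd3, Tomm40 and Immt were lost without any of 10, 10 and 12 libraries (unshifted log2 changes 0.15 to 0.16, 0.22 to 0.26 and -0.19 to -0.14), and Chchd3 turned to -0.08 after median-ratio scaling. After median-ratio scaling 0 import genes were higher, 5 were lower and the list passed as down (adjusted p = 1.22e-04).

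Of 33 calcium-handling and ion channel genes in P21 hearts, 5 were lower and 3 higher in cKO (10 and 5 adjusted over the list alone; 13 and 1 after median-ratio scaling), with the potassium channel genes Kcnj3 at -1.40, Kcnd2 at -0.98 and Kcnip2 at 0.54 relative to the median gene. Of 29 genes of mature cardiomyocytes, 5 were higher and 4 lower (6 and 4 adjusted over the list alone; 1 and 7 after median-ratio scaling), among them Tcap at -0.88, Myom2 at 0.93 and Cavin4 at 0.46. The list lay 0.24 below the median gene, while fry gave the direction up on the unshifted scale. Of 40 cytosolic ribosome genes 16 were higher (21 adjusted over the list alone; 1 after median-ratio scaling), such as Rpl3 (0.38) and Rplp1 (0.15). The direction of the list turned down after median-ratio scaling (adjusted p = 0.734). Of 4 skeletal muscle markers 2 were lower (2 lower and 1 higher adjusted over the list alone), with Tnni2 at -2.06. The other, Ckm, lost its call without any of 13 libraries (unshifted log2 changes -0.28 to -0.24, against -0.26 with all libraries). The list no longer passed after median-ratio scaling (adjusted p = 0.0774). Of 22 genes of the thyroid hormone and PPAR axis 1 was higher (1 adjusted over the list alone; 0 after median-ratio scaling), and the list lay 0.20 below the median gene. Camera adjusted p-values were 4.32e-08, 2.99e-04, 0.00575, 0.00457 and 0.0122. An estimated correlation gave an adjusted p of 0.134, 0.118, 0.736, 0.118 and 0.134. Without P21 WT 60 the ribosome list no longer passed (adjusted p = 0.106), nor did the thyroid list without P21 cKO 64 (0.0663).

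Further lists, among them the PI3K, AKT and mTOR pathway, which holds Pdpk1, and mitochondrial turnover, did not pass camera at P21. Whether the deleted gene was Pdpk1 was not given by the labels. Of 32 genes of the PI3K, AKT and mTOR pathway 11 were higher and 1 lower (15 and 1 adjusted over the list alone; 3 and 2 after median-ratio scaling; camera adjusted p = 0.0735), among them the receptor genes Igf1r at 0.79 and Insr at 0.55 and Akt2 at 0.22 and Akt1 at 0.15 relative to the median gene. Of 24 FOXO and atrophy targets 7 were higher (11 higher and 1 lower adjusted over the list alone; 3 and 2 after median-ratio scaling; 0.747), such as Gabarapl1 (0.49) and Bbc3 (0.51). Of 19 mitophagy genes 2 were higher (0 adjusted over the list alone; camera adjusted p = 0.358): Bnip3, at 0.17, lost its call without P21 WT 57, P21 cKO 55 or P21 cKO 64 (unshifted log2 changes 0.27, 0.28 and 0.43, against 0.38 with all libraries), and Sqstm1, at 0.08, without any of 14 libraries (0.17 to 0.35, against 0.30). After median-ratio scaling 6 mitophagy genes were lower, 0 were higher and the list passed as down (adjusted p = 0.00629), while fry on the unshifted scale gave it the direction up (0.0336). Of 15 genes of mitochondrial fission and fusion 1 was lower and 1 higher (1 and 0 adjusted over the list alone; 3 and 0 after median-ratio scaling; 0.0527, and 6.55e-04 after median-ratio scaling): Mief2, at -0.64, lost its call without P21 WT 57, P21 cKO 55 or P21 cKO 64 (unshifted log2 changes -0.43, -0.32 and -0.39, against -0.42 with all libraries), and Yme1l1, at 0.04, without any of 14 libraries (0.18 to 0.26, against 0.26). Of 24 fetal and stress genes 10 were higher and 2 lower (10 and 3 adjusted over the list alone; 7 and 3 after median-ratio scaling; 0.3), among them Gdf15, a stress-induced cytokine gene, at 1.65. Of 21 apoptosis genes 11 were higher (13 adjusted over the list alone; 3 after median-ratio scaling; 0.0652, and 0.0279 after median-ratio scaling), with Bcl2 at 1.36 and Trp53 at 0.35. Of 40 cell cycle genes 4 were higher (4 adjusted over the list alone; 2 after median-ratio scaling; 0.668), with Ccnd2 at 0.70 and Ccnd1 at 0.73. Of 14 cardiomyocyte markers 3 were higher (3 adjusted over the list alone), with Mybpc3 at 0.22, against 0 higher and 2 lower after median-ratio scaling. That list had a camera adjusted p of 0.134, and of 0.00342 after median-ratio scaling with the direction down.

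**Figure D3:**
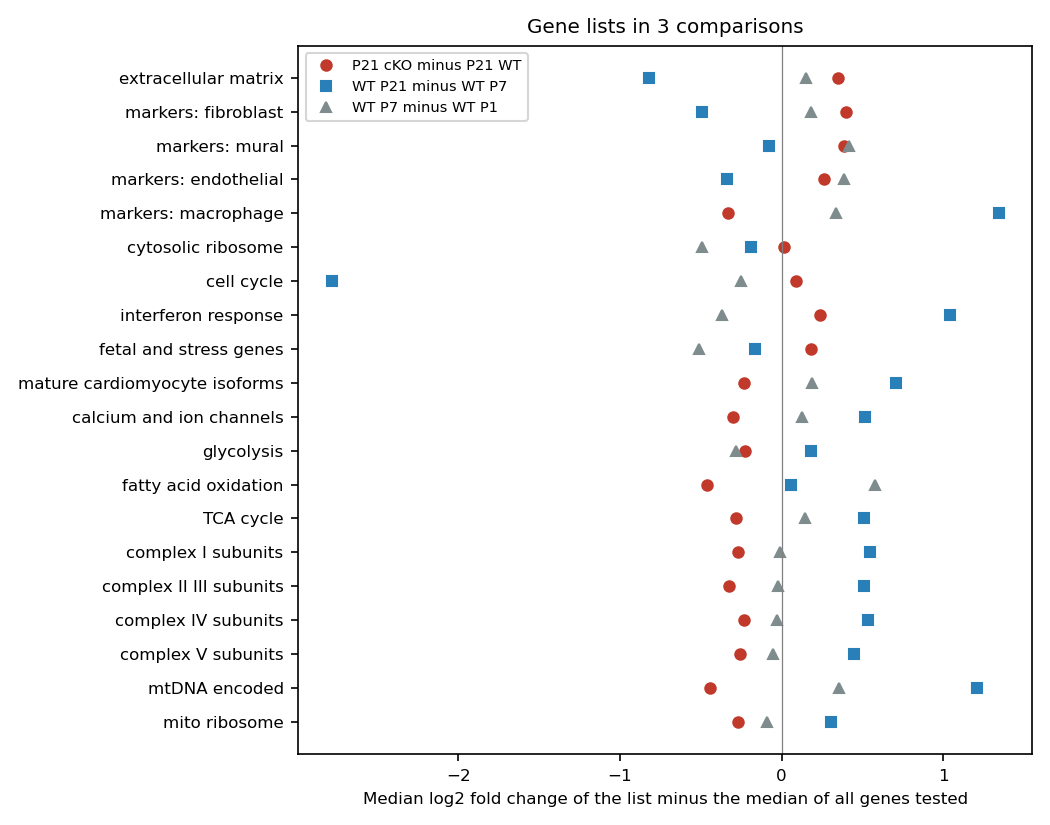
Median log2 fold change of 20 gene lists minus the median of all genes tested (horizontal axis) in 3 comparisons, 1 line per list. For P21 cKO against WT, fatty acid oxidation lay at -0.46 and the matrix list at 0.35, while for WT P21 against P7 the matrix list lay at -0.82 and the mitochondrial genome genes at 1.21. The cytosolic ribosome list, at 0.01 for P21 cKO, turned down after median-ratio scaling.

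Across all genes at P21, limma called 3155 of 14812, 2893 higher and 262 lower in cKO (91.7% higher), against 658 higher and 744 lower after median-ratio scaling (46.9% higher), 608 and 642 after quantile normalization, and 1970 and 305 with mitochondrial and haemoglobin genes removed. That removal went by symbol, and the abundant Gm genes named above stayed in. It thus does not show what all mitochondrial reads added. Of the 3155, 159 changed at least 2-fold on the log2(TPM + 1) scale, 121 higher and 38 lower. The simulated data recovered 88% of 2-fold and 42% of 1.4-fold changes at P21, all set in better expressed genes. Of 45 lists 19 passed camera, which compares a list with the other genes, 5 up and 14 down, while fry on the unshifted scale passed 21, 18 up and 3 down. With an estimated correlation 0 of the 19 passed (adjusted p 0.0597 to 0.736). Of the 35 ways to split these 7 libraries into 3 and 4, 2 gave at least as many genes, the real one included. The count of genes was 1459 against P21 WT libraries with plain numbers alone, 855 with library 63 added as cKO, 3236 with it added as WT, 1469 without P21 WT 57, 1658 without P21 cKO 59, 1802 without P21 cKO 64 and 5055 without P21 WT 60. With library 63 as cKO, Nppb (adjusted p = 0.0568), Ankrd1 (0.0591), Tnni2 (0.0631) and Myl1 (0.0907) no longer passed, nor did the ribosome and mural lists, and with it as WT all of these passed. Library 63 had P4ha3 at 0.05 TPM, against 574.83, 575.06 and 542.49 TPM in the P21 cKO libraries. Its placement as cKO thus put unlike libraries into that group.

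The difference between the P21 and P7 effects of the cKO was tested directly with an interaction term in the same limma model. Nppa had a P21 effect 4.51 ± 0.38 (SE) higher on the log2 scale than its P7 effect (adjusted p = 5.3e-05), Bex1 2.27, Nppb 2.13 (adjusted p = 0.00708) and Ankrd1 1.84. P4ha3 and Pold3, higher at both ages, had differences of 1.27 and 1.15. Ogdhl (-1.80), Tnni2 (-1.72), Myl1 (-1.28) and Csdc2 (-1.17) had lower P21 effects, while the differences for Pdpk1 (adjusted p = 0.9), Pdk1 (0.098), Lrtm1 (0.148) and Igsf1 (0.0621) did not pass. Fatty acid oxidation (camera adjusted p = 8.26e-14), complex I (6.38e-07) and calcium-handling genes (1.73e-07) were lower, and matrix genes (1.73e-07) and fibroblast markers (4.2e-06) higher, relative to other genes, in the P21 effect than in the P7 effect. With an estimated correlation their adjusted p was 0.0989, 0.508, 0.197, 0.367 and 0.367. Of the 45 lists, 20 passed camera for this difference, 6 up and 14 down, and 0 with an estimated correlation (adjusted p 0.0989 to 0.794), and fry passed 13, all up. In all, 1120 genes differed, 1043 up and 77 down, against 152 and 195 after median-ratio scaling and 158 and 154 after quantile normalization. The count was 144 with plain-number WT libraries alone, 621 with no filter on low values, 357 without P7 cKO 69 and 3123 without P21 WT 60. No gene passed in limma with library 63, whose P4ha3 level of 0.05 TPM was like that of WT, added as cKO, against 1003 with it as WT. In the model without that library 4361 genes had an unadjusted p under 0.05.

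Between P1 and P7, WT hearts gained Ucp3 messenger RNA and lost that of Mt2, Bmp10 and Nppa. Ucp3, which encodes a mitochondrial uncoupling protein (mm10, chromosome 7, 100472990 to 100486432), rose from 6.03 ± 5.14 TPM (n = 3) to 40.6 ± 8.69 TPM (n = 5), a log2 change of 2.93 ± 0.47 (SE; limma adjusted p = 3.83e-04). Fbp2 (2.82), Tuba8 (2.54), Rxrg (2.45), Mapt (2.43) and Scgb1c1 (2.31) rose too. Strit1, which encodes the SERCA-regulating micropeptide DWORF, was at 35.6 ± 31.9 TPM at P7 and was listed at 0 in all P1 libraries, so no fold change is given. Mt2, which encodes a metal-binding metallothionein (chromosome 8, 94172664 to 94173568), fell from 286.5 ± 44.4 TPM to 15.5 ± 2.9 TPM (-4.26, adjusted p = 3.33e-06). Hif3a fell from 15.6 ± 5.02 TPM to 0.556 ± 0.254 TPM (-3.38, adjusted p = 1.82e-07). Dlk1 (-2.72), Tent5b (-2.62), Bmp10 (-2.60) and Hey2 (-2.46) fell, as did Nppa, from 1582 ± 185 TPM to 347 ± 83.6 TPM (-2.44). Myl4, an atrial light chain gene (-2.59, adjusted p = 0.0267), no longer passed without P1 WT 2, P7 WT 1 or P7 WT 3 (-2.22, -2.74 and -2.05). Pdk1 fell from 54.2 ± 10.3 TPM to 40.6 ± 3.16 TPM (-0.38, adjusted p = 0.0303). This call was lost without P1 WT 1, P1 WT 2, P7 WT 1 or P21 WT 2 (-0.28, -0.32, -0.40 and -0.35). Pdpk1 did not pass (0.12, adjusted p = 0.482; -0.02 without P1 WT 3, 0.24 without P1 WT 2).

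Genes of fatty acid oxidation rose between P1 and P7: of 28, 19 rose and 1 fell (22 and 1 adjusted over the list alone), among them Cpt2 (0.92), Hadha (0.73) and Etfdh (0.67). Of 13 genes of the mitochondrial genome 6 rose (6 adjusted over the list alone), such as mt-Nd4 (0.67) and mt-Co1 (0.35). Of 40 cytosolic ribosome genes 39 fell (39 adjusted over the list alone), such as Rps16 (-0.58) and Rpl4 (-0.49). Of 22 glycolysis genes 12 fell and 5 rose (12 and 5 adjusted over the list alone), with Slc2a1 at -1.78 and Aldoc at -1.75. Of 12 genes of ketone and branched-chain amino acid use 7 fell and 2 rose (8 and 2 adjusted over the list alone), with Bcat2 at -0.89. Of 24 FOXO and atrophy targets 13 fell and 2 rose (13 and 2 adjusted over the list alone), with Klf15 at -2.23 and Bnip3 at -0.91. Of 24 fetal and stress genes 13 fell and 2 rose (14 and 2 adjusted over the list alone), with Nppb at -1.82. Myh7, at -1.23, is uncertain because it can share reads with Myh6. All 4 skeletal muscle markers fell (4 adjusted over the list alone), such as Mylpf (-1.18) and Ckm (-0.56). Camera adjusted p-values were 4.29e-10, 0.0101, 5.9e-19, 0.00808, 0.0077, 0.0077, 0.00603 and 0.0101 in this order. With an estimated correlation the adjusted p was 0.319 for fatty acid oxidation and skeletal muscle and 0.511 for the other 6. Within 1 title style the mitochondrial genome list did not pass, and the other 7 did.

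Further lists passed between P1 and P7 but lost that call when single libraries were left out. Of 24 interferon-response genes 10 fell (11 fell and 2 rose adjusted over the list alone), such as Ifi27l2a (-1.74) and Ifit3 (-1.21). Of 14 endothelial markers 9 rose and 1 fell (10 and 1 adjusted over the list alone), such as Kdr (1.07) and Vwf (-0.79); without P1 WT 1 their adjusted p was 0.096 and 0.0598. Of 29 genes of mature cardiomyocytes 11 rose and 3 fell (11 and 3 adjusted over the list alone), such as Ckmt2 (1.18) and Tnnt2 (-0.56). This call was lost without P1 WT 1, P1 WT 2 or P21 WT 60 (0.096, 0.0515 and 0.0674). Of 40 matrix genes 13 rose and 3 fell (13 and 3 adjusted over the list alone), such as Lum (1.03) and Dcn (0.83). This call was lost without P1 WT 1, P1 WT 3, P7 WT 1 or P21 WT 2 (0.0767, 0.165, 0.0556 and 0.0565). Of 10 atrial markers 5 fell (5 adjusted over the list alone), such as Bmp10 (-2.60) and Stard10 (-0.81). This call was lost without P1 WT 2, P7 WT 1 or P7 WT 3 (0.103, 0.0638 and 0.0796). Camera adjusted p-values were 0.016, 0.0172, 0.0399, 0.0369 and 0.0409. The adjusted p with an estimated correlation was 0.685, 0.511, 0.511, 0.734 and 0.643. Of 4 lymphocyte markers 2 rose (3 adjusted over the list alone), Ighm at 1.26 and Trbc2 at 1.04. Of 7 erythroid markers 1 rose (3 adjusted over the list alone), Tfrc at 1.19. Of 31 autophagy and lysosome genes 7 fell and 1 rose (7 and 1 adjusted over the list alone). Camera gave these 3 lists an adjusted p of 0.0409, 0.0205 and 0.0409, and of 0.511, 0.603 and 0.643 with an estimated correlation. Calls were lost for lymphocyte markers without any of 6 libraries (0.0569 to 0.103), for erythroid markers without P1 WT 1 or P21 WT 60 (0.096 and 0.0612) and for autophagy genes without any of 5 (0.052 to 0.0829). Within 1 title style only the atrial list of these 8 passed, so fatty acid oxidation was the only list that kept an up call. Of 40 cell cycle genes 13 fell and 10 rose (15 and 10 adjusted over the list alone), such as Ccnb2 (-1.06) and Ccnd2 (1.03). The list did not pass (camera adjusted p = 0.182).

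Across all genes between P1 and P7, limma called 4217 of 14812, 2043 higher and 2174 lower at P7, against 2306 and 2262 after median-ratio scaling and 2430 and 2228 after quantile normalization, and 506 changed at least 2-fold. Of 45 lists 16 passed camera, 7 up and 9 down, against 8 within 1 title style, 1 up and 7 down. Fry passed 23, 13 up and 10 down, and 0 of the 16 passed with an estimated correlation (adjusted p 0.319 to 0.734). Simulated data gave back 90% of 2-fold and 44% of 1.4-fold changes, all set in better expressed genes. All P1 titles had the letter style, and the model took the style difference from P7 and P21.

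Between P7 and P21, WT hearts lost messenger RNA of Tnni1 and Cdk1 and gained that of Ces1d and Art1. Tnni1, the troponin I gene of the fetal heart (mm10, chromosome 1, 135779434 to 135810989), fell from 890.2 ± 161 TPM (n = 5) to 1.31 ± 0.931 TPM (n = 4), a log2 change of -8.67 ± 0.23 (SE; limma adjusted p = 8.14e-13). Cdk1, which encodes the kinase that drives entry into mitosis, fell from 80.5 ± 8.53 TPM to 2.72 ± 1.07 TPM (-4.50, adjusted p = 6.03e-12). Mest fell from 196.2 ± 17.9 TPM to 6.54 ± 1.56 TPM (-4.75). Ube2c (-4.76), Cks2 (-4.41), Bex1 (-4.32), Knstrn (-4.30) and Rrm2 (-4.28) fell too. Ces1d (chromosome 8, 93166068 to 93197838) rose from 0.836 ± 0.649 TPM to 34.5 ± 8.26 TPM (4.32 ± 0.29, adjusted p = 3.79e-09), Art1 from 6.64 ± 1.86 TPM to 105.1 ± 8.63 TPM (3.87, adjusted p = 1.27e-11) and Rpl3l, a ribosomal protein gene specific to striated muscle, from 25.4 ± 10.6 TPM to 167.3 ± 37 TPM (2.84). Ogdhl (3.13), Xdh (2.90), Csdc2 (2.77), Mgl2 (2.69) and Phkg1 (2.50) rose as well. Pdk1 fell from 40.6 ± 3.16 TPM to 26.5 ± 2.12 TPM (-0.60, adjusted p = 6.14e-05). Pdpk1 fell from 9.78 ± 1.89 TPM to 6.86 ± 0.629 TPM (-0.47, adjusted p = 3.41e-04), which turned to 0.02 after median-ratio scaling and 0.06 after quantile normalization.

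All 40 cell cycle genes fell between P7 and P21 (40 adjusted over the list alone; 40 after median-ratio scaling), with Rrm2 at -3.81, Cdc20 at -3.68 and Bub1b at -2.88 relative to the median gene. Of 40 matrix genes 34 fell (35 adjusted over the list alone; 30 fell and 2 rose after median-ratio scaling), with Postn at -3.24 and Fn1 at -2.35. Of 21 genes of cholesterol synthesis 19 fell (19 adjusted over the list alone; 13 fell and 1 rose after median-ratio scaling), with Sqle at -1.41 and Hmgcs1 at -0.52. All 40 cytosolic ribosome genes fell (40 adjusted over the list alone; 10 after median-ratio scaling), with Rpl3 at -1.18 and Rps16 at -0.38. The list did not pass after median-ratio scaling (adjusted p = 0.0697). Camera adjusted p-values were 3.17e-16, 4.92e-05, 0.0255 and 1.93e-05. An estimated correlation gave an adjusted p of 0.169, 0.474, 0.585 and 0.572.

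Macrophage, interferon-response and mature heart genes rose between P7 and P21 relative to the median gene. Of 14 macrophage markers 11 rose (11 adjusted over the list alone; 13 after median-ratio scaling), with Folr2 at 2.81, Lyz2 at 2.11 and Cd163 at 2.07. Of 24 interferon-response genes 19 rose and 1 fell (19 and 1 adjusted over the list alone; 23 and 0 after median-ratio scaling), with Ifi27l2a at 2.87 and Oas2 at 2.27. Of 29 genes of mature cardiomyocytes 15 rose and 5 fell (15 and 5 adjusted over the list alone; 23 and 1 after median-ratio scaling), with Adra1a at 2.17, Tcap at 2.13 and Cox7a1 at 1.84. Of 33 calcium-handling and ion channel genes 12 rose and 9 fell (12 and 9 adjusted over the list alone; 23 and 4 after median-ratio scaling), with Kcnd2 at 2.10 and Kcnd3 at 2.08. Of 12 genes of ketone and branched-chain amino acid use 8 rose and 2 fell (8 and 2 adjusted over the list alone; 10 and 1 after median-ratio scaling), with Oxct1 at 1.84 and Bckdha at 1.60. Camera adjusted p-values were 4.45e-14, 4.49e-16, 4.17e-11, 2.63e-08 and 1.29e-08. The adjusted p with an estimated correlation was 0.0196 for macrophage markers and 0.00651 for mature cardiomyocyte genes, which still passed, and 0.125, 0.125 and 0.085 for the other 3. Of 7 erythroid markers 0 rose and 1 fell (0 and 0 adjusted over the list alone; 5 and 0 after median-ratio scaling), Slc4a1, a call that was lost without P7 WT 3, P7 WT 76, P21 WT 2 or P21 WT 60 (unshifted log2 changes -0.38, -0.33, -0.33 and -0.35, against -0.42 with all libraries). The erythroid list passed as up (camera adjusted p = 0.0175, and 0.453 with an estimated correlation), but not without P21 WT 3 or P21 WT 57 (0.0556 and 0.0777) or after median-ratio scaling (0.123). Of 4 skeletal muscle markers 2 rose (2 adjusted over the list alone; 2 after median-ratio scaling), with Ckm at 0.70. The list passed (camera adjusted p = 0.0156, and 0.125 with an estimated correlation), but not after median-ratio scaling (0.0995). Other immune lists did not pass and, without scaling, had 0 members that rose. All 3 thymocyte markers fell (3 adjusted over the list alone; 3 after median-ratio scaling; camera adjusted p = 0.227), with Cd1d1 at -1.73. Of 5 neutrophil markers 2 fell (2 adjusted over the list alone; 1 of 4 after median-ratio scaling; 0.642), Ngp at -0.23 and Ltf at -0.06. Of 13 inflammation genes 2 fell (2 adjusted over the list alone; 2 fell and 4 rose after median-ratio scaling; 0.0655), Vcam1 at -1.03 and Sele at -0.79. Of 4 lymphocyte markers 0 were called (0 adjusted over the list alone; 1 of 5 rose after median-ratio scaling; 0.21).

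Of 13 genes of the mitochondrial genome 9 rose between P7 and P21 (9 adjusted over the list alone; 10 after median-ratio scaling), with mt-Nd2 at 1.31 and mt-Nd4 at 1.21 relative to the median gene (camera adjusted p = 6.17e-11, and 0.00651 with an estimated correlation). Nuclear respiratory chain genes followed the scaling: of 36 complex I genes 11 rose and 1 fell (5 and 1 adjusted over the list alone; 35 and 0 after median-ratio scaling), with Ndufs7 at 0.87. Of 13 genes of complexes II and III 4 rose and 1 fell (4 and 1 adjusted over the list alone; 13 and 0 after median-ratio scaling), with Sdhb at 0.75. Of 14 complex IV genes 4 rose and 3 fell (3 and 3 adjusted over the list alone; 12 and 2 after median-ratio scaling), with Cox8a at -0.48 beside Cox7a1. Of 16 complex V genes 0 rose and 4 fell (0 and 3 adjusted over the list alone; 13 and 1 after median-ratio scaling), with Atpif1 at -0.71 and Atp5b at 0.28. Camera gave complex V the direction up (adjusted p = 0.0417, and 0.585 with an estimated correlation). That call was lost without P7 WT 3, P7 WT 77, P21 WT 2 or P21 WT 57 (0.0677, 0.0615, 0.0595 and 0.0835), and the direction was down with quantile normalization (0.734) and fry (0.0501). Of 17 citric acid cycle genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; 16 and 0 after median-ratio scaling), with Sucla2 at 0.79 and Idh2 at -0.19. Camera adjusted p-values for complex I, complexes II and III, complex IV and the citric acid cycle were 1.87e-09, 6.48e-04, 9.44e-04 and 2.08e-04. With an estimated correlation the adjusted p was 0.399, 0.353, 0.444 and 0.247. Of 28 genes of fatty acid oxidation 16 fell and 3 rose (16 and 3 adjusted over the list alone; 6 and 14 after median-ratio scaling), with Cpt1b at -0.42 and Lpl at 1.51. The list did not pass (camera adjusted p = 0.605). Fry, which tests the unshifted scale, gave complex IV the direction down (adjusted p = 0.802).

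Across all genes between P7 and P21, limma called 10743 of 14812, 1200 higher and 9543 lower at P21, against 3953 and 4144 after median-ratio scaling, 3964 and 4042 after quantile normalization, and 1523 and 8808 with mitochondrial and haemoglobin genes removed. Of the 10743, 2230 changed at least 2-fold, 296 higher and 1934 lower. Of 45 lists 20 passed camera, 16 up and 4 down, and 3 passed with an estimated correlation. Fry on the unshifted scale passed 34, 7 up and 27 down. Simulated data gave back 97% of 2-fold and 56% of 1.4-fold changes, all set in better expressed genes.

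The P21 effect of the cKO ran against the WT change from P7 to P21, with genes such as Bex1, which fell in WT and was higher in cKO, and Ogdhl and Csdc2, which rose in WT and were lower in cKO. The estimates were made with separate WT libraries, plain-number titles for the cKO effect and letter titles for the WT change. Pearson's r across 14812 genes was -0.249 and Spearman's rho -0.304, and r was -0.199 without P21 WT 57. Of 8721 genes that fell in WT, 7620 (87.4%) had a higher estimate in P21 cKO. Of 822 that rose, 447 (54.4%) had a lower one. After median-ratio scaling the shares were 75.5% and 70.0%. These shares count signs, whether or not the cKO change passed. The median gene was itself 0.22 higher in P21 cKO, and no share over all genes was computed, so 87.4% alone does not show opposition. Of the genes called for the cKO in this fit, 1217 of 1307 higher ones fell in WT by sign and 98 of 152 lower ones rose. Of 9543 genes changed in WT, 8721 fell. The P7 effect and the WT change from P1 to P7 had an r of -0.0743 and a rho of -0.00551. By the sign of the estimates alone, 48.7% of genes that fell in WT were higher in P7 cKO and 50.1% of those that rose were lower. In the main model only 3 genes passed at P7.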

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

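The tests of the chromosome 7 locus, of paralogs, of a response to PDK1 loss, of abundant genes, of the share of cardiomyocytes, of a haplotype and of a batch were chosen after the result was seen, and those of gene length and of the splits of libraries before.

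P4ha3 and Pold3 lie close together on chromosome 7 and were higher in cKO at both ages. A local change at the locus fits the pattern at P7: 6 of 32 other genes within 1 Mb (18.8%) had an unadjusted p under 0.05, against 3.16% elsewhere (Fisher's exact test, one-sided p = 4.57e-04). The test ignored direction. Lipt2, Kcne3, Pgm2l1, Ppme1 and Map6, the last chosen after its values were seen, were lower in cKO, opposite to P4ha3 and Pold3, and Gm35082 was higher. Of the 6, Gm35082 (1.88) and Lipt2 (-0.61) passed in limma at P21 (adjusted p = 7.63e-04 and 0.0127). The Fisher test was not run at P21, where 5557 of 14812 genes had an unadjusted p under 0.05. Reads shared with the paralogs P4ha1 and P4ha2, genes chosen after their values were seen, were excluded, since the lowest ratio of P4ha3 to their sum in cKO libraries was 15.3. The test of a response to loss of PDK1 could not tell: P4ha3 was above every WT library in all 6 cKO libraries, as a local change would also give.

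Most genes called at P21 were higher in cKO. With the 10 most abundant genes removed 77.4% of called genes were still higher, and 66.2% to 87.5% with single libraries also left out. That range cannot tell whether a few abundant genes set the direction, while median-ratio scaling gave 46.9%. A fibroblast minus macrophage marker score differed between groups (2.77 ± 0.112 in cKO, n = 3, 2.14 ± 0.255 in WT, n = 4, exact two-sided permutation p = 0.0286). Markers of these 2 cell types therefore did not rise alike, as a lower share of cardiomyocytes alone would predict. The test cannot exclude that cause, because the 2 lists had already differed in these libraries when it was chosen. Also, 7 of the 14 fibroblast markers are matrix genes, and heart tissue expresses them. Gene length could not be told apart, with a Spearman's rho of 0.126.

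WT libraries of the 2 title styles differed in a few genes. A haplotype around Pdpk1 on chromosome 17 fits: 8 of 28 positioned genes called between styles at P7 lay within 10 Mb of Pdpk1 (Fisher's exact test, one-sided p = 4.84e-08). The test of a batch could not tell, with 0.209% of genes called (31), 5 of them also at P21. These were Atp6v0c-ps2, Rps2-ps10, Rps2-ps6, Rnps1-ps and Gm11249, chosen after their values were seen. The test counted them as outside the window by their own positions. Rnps1-ps can share reads with Rnps1, a gene near Pdpk1 on chromosome 17 that was also called at P7. A batch and a haplotype are thus not told apart by these genes. The letter code of the P21 titles was B6.

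Splits of the same libraries showed which counts other groupings also reach. Chance was called excluded where under 5 in 100 splits reached a count, with no adjustment for the number of counts tested. At P7, 2 of 56 splits gave at least the 3 genes of the real one. This met the level of 5 in 100, but another split gave 7 genes, so the count alone is weak ground against chance. For the lists, 51 of 56 splits gave at least the 3 of the real one (highest other 17), so chance was not excluded. At P21, 2 of 35 gave at least 3155 genes (highest other 4160) and 6 of 35 at least 19 lists (highest other 24), and chance was not excluded for either. For WT P7 against P1, 1 of 56 gave at least 4217 genes (highest other 2; excluded) and 13 of 56 at least 16 lists (highest other 18; not excluded). For WT P21 against P7, 1 of 99 fitted splits gave at least 10743 genes (highest other 9655; excluded) and 29 of 99 at least 20 lists (highest other 28; not excluded). For the difference between the P21 and P7 effects, 3 of 100 draws gave at least 1120 genes. This met the level of 5 in 100, although another draw gave more genes (2103).

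A single library stood apart in 9 of 73 sets, each a named gene or a library measure in P7 WT or P21 WT. About 1 in 20 is expected by chance for normally spread values. That rate may not hold here, since both groups mix the 2 title styles. The value is the gap to the nearest library over the range. Bmp10 in P7 WT 77 was at 1.16 TPM (others 0.01 to 0.13; 0.896). In P7 WT 1, Art1 was at 3.34 TPM (7.18 to 7.71; 0.879), Csdc2 at 2.47 TPM (3.47 to 3.74; 0.787) and Cks2 at 82.35 TPM (51.59 to 55.61; 0.869). In P21 WT 57, Nppa was at 384.28 TPM (169.86 to 200.94; 0.855) and Uckl1os at 5.04 TPM (8.06 to 8.21; 0.953). In P21 WT 3, Mrpl48-ps was at 0.26 TPM (others 0; gap over range 1) and Mgl2 at 6.80 TPM (8.52 to 8.72; 0.896). Rrm2 in P21 WT 60 was at 1.94 TPM (1.29 to 1.32; 0.954).

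The cKO effect differed between P21 and P7 in 1120 genes. The log2 differences were 1.27 for P4ha3, 1.15 for Pold3, 4.51 for Nppa, 2.13 for Nppb, 2.27 for Bex1, 1.84 for Ankrd1, 1.85 for Tmem171, -1.94 for Uckl1os, -1.72 for Tnni2, -1.80 for Ogdhl, -1.28 for Myl1 and -1.17 for Csdc2. Lists with a lower P21 effect relative to other genes (camera adjusted p from limma; none of the 20 passed with an estimated correlation, adjusted p 0.0989 to 0.794) were complex I (6.38e-07), complexes II and III (3.4e-05), complex IV (0.00585), complex V (0.00471), mitochondrial genome (4.2e-06), citric acid cycle (1.52e-07), fatty acid oxidation (8.26e-14), glycolysis (5.67e-04), mitochondrial ribosome (3.4e-05), mature cardiomyocyte genes (1.15e-04), calcium handling (1.73e-07), thyroid and PPAR axis (0.00777), macrophage markers (0.00377) and skeletal muscle markers (0.0276). Those with a higher one were matrix (1.73e-07), apoptosis (0.0219), cytosolic ribosome (0.00368), fibroblast (4.2e-06), endothelial (0.0277) and mural markers (0.0284).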

How the results depend on the processing

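Of 7812 settings of named and list genes 7392 kept their call, and of 1895 settings of lists 1687 did. The alternative without P21 WT 57 and P21 cKO 55 was chosen after seeing the data. Where values moved the cause was not tested, and count-based tests were not run because the file held no counts.

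Genes called at P7 (3) numbered 9 with no filter, 5 with mitochondrial and haemoglobin genes removed, 5 with no style term, 0 with library 63 as cKO, 12 with array quality weights, and 2 to 7 with single libraries left out. At P21 (3155) they numbered 1402 with median-ratio scaling, 1250 with quantile normalization, 1459 within 1 title style, 855 with library 63 as cKO, 5702 with weights, 159 at 2-fold, 1340 without P21 WT 57 and P21 cKO 55, and 1469 to 5055 with single libraries left out. For the difference of the effects (1120) they numbered 621 with no filter, 347 with median-ratio scaling, 312 with quantile normalization, 656 with mitochondrial and haemoglobin genes removed, 144 within 1 style, 0 with library 63 as cKO, 5212 with weights, 129 at 2-fold, 645 without P21 WT 57 and P21 cKO 55, and 357 to 3123 with single libraries left out. At 2-fold there were 506 genes for WT P7 against P1 and 2230 for P21 against P7.

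Lists at P7 (3) numbered 5 with no filter, 1 with quantile normalization, 10 with no style term, 1 with the replicate block, 1 with library 63 as cKO, 0 with an estimated correlation, 0 with fry, 7 without P21 WT 57 and P21 cKO 55, and 0 to 4 with single libraries left out. With an estimated correlation 0 lists passed at P21 and 0 for WT P7 against P1, which had 8 within 1 style (1 up, 7 down), and 3 passed for WT P21 against P7, which had 34 with fry (7 up, 27 down). At P21 fry passed 21 (18 up, 3 down). The replicate block gave 2 genes at P7, 2734 at P21 and 755 for the difference. Same-numbered libraries had correlations of -0.0822, -0.0951, -0.00465, 0.0155 and 0.0657, which gave no sign that the numbers pair libraries. The check cannot exclude pairing. With 2 letter-title libraries each at P7 and P21, values for the same and the other number were equal with opposite sign.

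Pdpk1 at P21 went from -0.15 to -0.3692 with median-ratio scaling and -0.391 with quantile normalization. The correlation at P21 (-0.249) was -0.1957 with a pseudocount of 0.1, -0.3145 with no filter, -0.2703 with the 5 TPM filter, -0.2706 with median-ratio scaling, -0.3039 as Spearman's rho, -0.3134 over genes changed in WT, and -0.2656 to -0.1993 with single libraries left out. At P7 (-0.0743) it was -0.06122 with no filter, -0.09637 with the 5 TPM filter, -0.0631 with mitochondrial and haemoglobin genes removed, -0.005513 as Spearman's rho, -0.08631 over genes changed in WT, and -0.08728 to -0.0535 with single libraries left out.

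Directions turned for Pdpk1 in WT P7 against P1 (-0.06901 with no style term, -0.02022 without P1 WT 3, against 0.236 without P1 WT 2) and in WT P21 against P7 (0.02344 with median-ratio scaling, 0.0623 with quantile normalization), for mt-Nd5 in WT P7 against P1 (-0.01935 with quantile normalization), for Chchd3 at P21 (-0.08482 with median-ratio scaling, -0.008469 with quantile normalization), and with median-ratio scaling for Ndufc2 (0.06775) and Sdhd (0.2351) in WT P21 against P7. Among lists at P21 the direction turned for mature cardiomyocyte genes (adjusted p = 0.7789) and the thyroid and PPAR axis (0.3953) with fry and for the cytosolic ribosome with median-ratio scaling (0.7335). In WT P21 against P7 it turned with fry for complex IV (0.8018), complex V (0.05011), the NRF2 list (0.01392) and the thyroid and PPAR axis (2.77e-04), and with quantile normalization for complex V (0.7341).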

Other observations

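Antioxidant and thyroid-axis genes moved in WT hearts between P7 and P21. Of 24 NRF2 targets 12 fell and 6 rose (12 and 6 adjusted over the list alone; 2 and 14 after median-ratio scaling), with Gsta3, a glutathione transferase gene, 1.92 and Prdx3 0.88 above the median gene (camera adjusted p = 0.0242, and 0.353 with an estimated correlation). Of 22 genes of the thyroid hormone and PPAR axis 9 rose and 9 fell (10 and 9 adjusted over the list alone; 13 and 7 after median-ratio scaling), with Hr at 2.02 and Rara at -0.79 (0.00203, and 0.0568 with an estimated correlation). Of 24 FOXO and atrophy targets 8 rose and 9 fell (8 and 9 adjusted over the list alone; 14 and 3 after median-ratio scaling), with Bcl6 at 2.19 and Klf15 at 1.86 (limma camera adjusted p = 1.12e-04, and 0.247 with an estimated correlation).

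Library 63 had Nppa at 190.83 TPM, Nppb at 111.64 TPM, P4ha3 at 0.05 TPM and Pold3 at 5.29 TPM, and its 10 most abundant genes held 39.58% of TPM. The P21 cKO libraries had Nppa at 8176.18 to 15241.29 TPM and Nppb at 856.35 to 1041.48 TPM. Their P4ha3 was at 542.49 to 575.06 TPM and their Pold3 at 110.2 to 148.75 TPM. In these genes library 63 was like the P21 WT libraries, which argues against its cKO label. Library P1 WT 3 had Xist, the X-inactivation transcript, at 18.37 TPM and the Y-linked Ddx3y at 3.77 TPM together, while each other grouped library had at most 0.06 TPM of the one or 0.03 TPM of the other. Ddx3y without Xist was found in P7 WT 1, 72 and 77, P7 cKO 82, P21 WT 2 and 57 and P21 cKO 55, and in no P1 library. The groups thus differed in their mix of sexes, and what sex added to the comparisons was not tested.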
